A study of Mus musculus with 8 samples.

How the data were processed

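RNA was measured by bulk sequencing of hearts from 2-week-old mice labelled as knockouts (Lmna-/-) of Lmna, the gene of lamins A and C. Of the 8 libraries, 3 came from knockout hearts whose labels name no vector, called untreated below, and 5 from knockout hearts given an adeno-associated virus of serotype 9 (AAV9) carrying wild-type LMNA. Total RNA was extracted with a miRNeasy kit and made into libraries with an Illumina TruSeq kit, per the labels' protocols. The strain is given as mixed. The sex, litter, vector dose and library batch of the animals are not given in the sources used here.

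The deposited values are raw counts of reads per gene, whole numbers with no normalization, 1 table per library. The submitters' processing notes name TopHat2, HTSeq, edgeR and limma, without versions or roles, and the genome builds GRCm38 and mm10. Per the deposited tables, reads were counted without strand over 53465 Ensembl genes and 87774 NONCODE genes. NONCODE is a catalogue of noncoding transcripts, here its version 5. Each table ends in 5 summary lines, for example reads outside every feature and reads that overlap more than 1 feature. These lines were kept out of library sizes and tests. Reads outside features made up 12.05 to 24.69% of the reads on features, outside features or ambiguous together, and ambiguous reads 21.03 to 26.37%. Counting without strand means that reads of a gene and of an overlapping or antisense gene cannot be told apart, and a read that overlaps both is dropped as ambiguous. NONCODE also catalogues long noncoding RNAs that Ensembl lists.

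Gene symbols, coordinates, transcript lengths and GC content came from GENCODE M21, which is on GRCm38. Of the 53465 Ensembl identifiers, 53274 matched. NONCODE coordinates were not used here, so overlaps of named genes with NONCODE genes were not checked. Overlaps with other annotated genes are pointed out below for some genes only. Other named genes have them too, among them Acadvl, Cdkn1a, Myl4, Psmb8 and Ndufa4l2.

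Counts per library on features ran from 21439956 to 26492443. Low counts were removed with edgeR's filterByExpr given the groups, which left 26717 features. The main test was edgeR 4.0.16 (R 4.3.3): TMM scaling over Ensembl and NONCODE features together, robust quasi-likelihood fits with 1 term for the group, and Benjamini-Hochberg adjustment over the 26717 features at 0.05. Log2 fold changes are AAV9-LMNA over untreated knockout. CPM values were computed from the deposited counts and TMM library sizes. Means are given with the SD between libraries. The labels do not state that each library came from a different animal, so p-values measure the spread between these libraries, which may in part be technical.

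Before the data were examined, 20 pathway lists and 14 cell type marker lists were fixed, with 992 entries, of which 984 matched a gene in the tables, 1 of them by another symbol. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 20 or the 14 lists, and again with an estimated correlation and with fry. The rule for named genes was fixed at the same time: Lmna, the 10 rising and 10 falling genes with the largest fold among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, 3 NONCODE features each way with the smallest p, and up to 4 called members of each list, or up to 2 uncalled members of a list with none. Gm and Rik names were left out of the first part. From the genes so named 4 are not reported here, and they were not replaced; the counts of each list include them. Genes named outside that rule were chosen after their values were seen. Library measures were compared with exact permutation tests over the 56 ways to split 8 libraries into 3 and 5.

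The alternatives set beforehand were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a minimum of 1 CPM in at least 3 libraries, Ensembl or NONCODE features alone, 1 surrogate variable (sva 3.50.0), an Xist covariate, and each library left out in turn. Added after the data were seen were a correction of each library for transcript length and GC content (a loess curve with a span of 0.5 on Ensembl genes, passed to edgeR as offsets), a fit without knockout replicates 6 and 8, and camera with an estimated correlation on Ensembl features alone.

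The scripts were tested on simulated counts for the 26717 features of this comparison. Of the genes raised or lowered 4-fold, 95.5% of 66 were recovered, against 50.7% of 67 at 2-fold and 4.48% of 67 at 1.5-fold. Of 112 calls, 9 were on unchanged features (8.04%). A list of 40 raised genes had a camera p of 5.80e-33 and an unchanged list of 40 one of 0.836. The simulated genes were drawn independently, so this does not test camera on lists whose genes move together. The estimated correlation of the interferon list, for example, was 0.74. A simulated length trend with a Spearman correlation of -0.751 fell to -0.0094 after the correction. No library pair differed by less than sampling noise: the chi-square per degree of freedom within groups was at least 9.97. Tables were joined with Python 3.11.15 and plots drawn with matplotlib 3.10.9.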

Results

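Gene expression was measured by RNA sequencing in hearts of 2-week-old Lmna knockout mice, 3 libraries from untreated knockout hearts (replicates 6, 7 and 8) and 5 from knockout hearts given AAV9 carrying wild-type LMNA (replicates 1 to 5). Loss of lamins A and C, filament proteins that line the inner face of the nuclear envelope, causes heart disease in mice and people. AAV9 is a vector that delivers genes to heart muscle. The comparison of both groups addresses which coding and long noncoding RNAs differ when AAV9 carrying LMNA is given to hearts that lack lamin A/C. No wild-type hearts were analysed here, so the direction of a change relative to a normal heart is not given. No hearts given a control vector were analysed either, so an effect of LMNA cannot be told apart from one of AAV9 itself. Counts on features averaged 22590000 ± 1315000 (SD, n = 3) in untreated and 23390000 ± 1948000 (SD, n = 5) in AAV9-LMNA libraries, a difference within the spread between libraries (exact permutation test, two-sided p = 0.5).

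The groups differed in where reads fell. Reads outside every annotated feature made up 19.9% ± 4.2 (SD, n = 3) in untreated and 12.4% ± 0.367 (SD, n = 5) in AAV9-LMNA libraries, a ratio of 1.60. NONCODE features took 3.38% ± 0.642 of the counts against 2.16% ± 0.0765, a ratio of 1.56. Both differences had an exact two-sided permutation p of 0.0179, the smallest that 56 splits allow, and a Benjamini-Hochberg adjusted p of 0.0536 over 6 measures. Untreated replicate 6 had the most reads outside features (24.7%), and replicates 7 and 8 had 16.8% and 18.4%. On the first principal component, with 49.6% of the variance, untreated replicate 6 lay at -121.9, replicate 8 at -69.0 and replicate 7 at -19.6, and the AAV9-LMNA libraries lay between 28.3 and 57.5. Untreated replicate 7 correlated more with the AAV9-LMNA libraries (mean r = 0.967 across features) than with its own group (0.953).

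**Figure D1:**
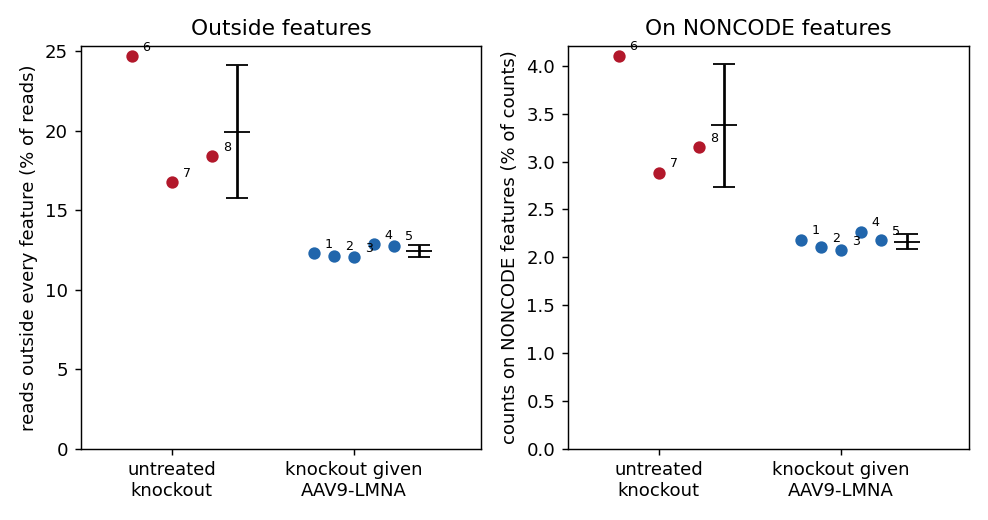
Reads outside every feature (left, percent of reads) and counts on NONCODE features (right, percent of counts) in each library. Points are libraries with their replicate numbers, and bars are the group mean and SD. Every untreated library (at least 16.75% and 2.886%) lies above every AAV9-LMNA library (at most 12.85% and 2.269%).

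Lmna (ENSMUSG00000028063, GRCm38 chromosome 3, 88480147 to 88509956, minus strand) was reported first, as a check of the labels. It was higher in each AAV9-LMNA library than in any untreated library. The untreated libraries held 46.4, 68.7 and 32.3 CPM (replicates 6, 7 and 8; mean 49.1 ± 18.3, SD, n = 3), and the AAV9-LMNA libraries 393, 227, 325, 312 and 747 CPM (replicates 1 to 5; mean 401 ± 202, SD, n = 5). The log2 fold change was 3.03 with a standard error of 0.46, or 8.16-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00486). Set against untreated replicate 7 alone, without replicates 6 and 8, it was 2.56 and not called (edgeR adjusted p = 0.191). The untreated libraries, whose labels name no vector, held 3452 raw Lmna counts together. Lmna reads in the AAV9-LMNA libraries thus need not all come from the vector, and the source of the untreated reads was not tested. The species and sequence of the LMNA insert are not given in the sources used here. Of the vector reads, the count covers only those that align to the mouse gene.

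**Figure D2:**
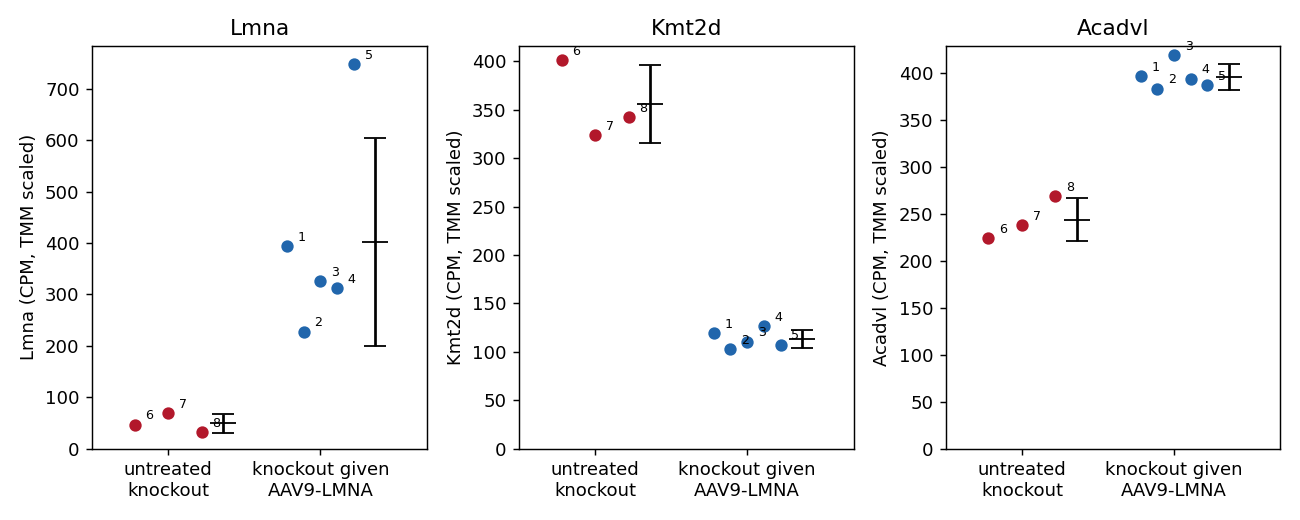
CPM of Lmna, the histone methyltransferase gene Kmt2d and the fatty acid oxidation gene Acadvl in each library, with replicate numbers, and the mean and SD of each group. Lmna (mean 49.1 against 401 CPM) and Acadvl (244 against 396) were higher and Kmt2d (356 against 113) lower in AAV9-LMNA libraries, with no overlap between groups.

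Giving AAV9-LMNA was accompanied by changes in 6858 of 26717 features tested, 2843 higher and 4015 lower (edgeR quasi-likelihood, adjusted p under 0.05). Coding genes mostly rose, 2535 higher against 837 lower of 13785 tested, and NONCODE features mostly fell, 150 higher against 3081 lower of 11461. That split depended on scaling. With Ensembl features scaled and tested alone, the median log2 fold change of the same features shifted by -0.19 and 1967 genes were called, 660 higher and 1307 lower. The main test called 3627 of these Ensembl features, 2693 higher and 934 lower. With NONCODE features alone the shift was 0.57, and 902 were higher and 883 lower. Group ranges did not overlap in 29.9% of features, against 3.57% by chance. Fewer features were called without untreated replicate 6 (4227), AAV9-LMNA replicate 2 (4216) or AAV9-LMNA replicate 3 (4227), and 2143 without untreated replicates 6 and 8.

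Among genes named by the fixed rule, the steepest rises after Lmna were in Fos, H2-Eb1, H2-T23 and Angptl4. Fos, an immediate early transcription factor (chromosome 12, 85473890 to 85477273), went from 8.05 ± 9.69 CPM (SD, n = 3) to 50.4 ± 13.7 (SD, n = 5), a log2 fold change of 2.64 with a standard error of 0.75 (edgeR adjusted p = 0.0393). Its call was lost without any 1 library other than untreated replicate 7. The major histocompatibility genes H2-Eb1 (class II) and H2-T23 (class I) rose by 2.64 and 2.19 on the log2 scale. Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 2.17. Cd300c2, an immune receptor gene, rose by 2.05, the chemokine gene Cxcl9 by 1.85, and Fam81a, Kbtbd13 and Lurap1l by 1.99, 1.84 and 1.73. All 10, Lmna included, also rose with Ensembl features scaled alone. Without untreated replicates 6 and 8, Angptl4, Kbtbd13 and Lurap1l kept their calls and the other 7 lost theirs.

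The steepest falls apart from atrial genes were in Baiap2l1, Naca, Dnah3, Eppk1, Hif3a, Zfp469 and Tead1. Naca (chromosome 10, 128035575 to 128048637), a chaperone subunit whose muscle form carries a large extra exon, fell from 274 ± 87.2 CPM (SD, n = 3) to 40.1 ± 5.33 (SD, n = 5), a log2 fold change of -2.77 with a standard error of 0.18 (edgeR adjusted p = 4.3e-05). Tead1 (chromosome 7, 112679318 to 112906807), a transcription factor of the Hippo pathway, fell from 250 ± 74.8 to 70.0 ± 8.47 CPM, a log2 fold change of -1.84 with a standard error of 0.17 (edgeR adjusted p = 0.00023). Hif3a, a hypoxia-inducible factor gene, had a log2 fold change of -2.49, Eppk1 (epiplakin) of -2.49, Zfp469 of -2.04, Dnah3 of -2.54 and Baiap2l1 of -3.17. Baiap2l1, Dnah3 and Eppk1 overlap other annotated genes, so their counts are uncertain. Without untreated replicates 6 and 8 the calls of Baiap2l1, Dnah3 and Hif3a were lost, and Naca (-2.30), Tead1 (-1.40), Eppk1 and Zfp469 kept theirs.

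Several genes of the atrium fell, and untreated replicate 8 set the size of that change. Of 16 tested genes on the atrial cardiomyocyte list, 0 rose, 5 fell and 11 were not called (5 also fell adjusted over the list alone). The 5 became 1 without AAV9-LMNA replicate 3, 2 without AAV9-LMNA replicate 2, 4 or 5, 3 without untreated replicate 8 or AAV9-LMNA replicate 1, and 5 or 7 without untreated replicate 6 or 7. Bmp10, a growth factor of the atrium, held 1.60, 1.15 and 82.1 CPM in untreated replicates 6, 7 and 8, and 3 counts in all 5 AAV9-LMNA libraries together. Its ratio of untreated to AAV9-LMNA was 1022, with a 95% exact counting interval of 349 to 4961 that leaves out the spread between libraries. Its log2 fold change of -9.80 became -5.45 without untreated replicate 8 and stayed called (edgeR adjusted p = 0.0208 and 0.00289). Myl7, the atrial regulatory light chain, held 4.51, 1.71 and 308 CPM against at most 0.796 in any AAV9-LMNA library. Its log2 fold change of -7.87 became -2.80 without untreated replicate 8 and stayed called (edgeR adjusted p = 0.0273 and 0.0068). Myl4, the atrial essential light chain, held 399 CPM in replicate 8 and at most 9.11 in the other untreated libraries. Its log2 fold change of -4.91 became -0.73 without replicate 8, and that call was lost (edgeR adjusted p = 0.0767). Gnao1 and Nr2f2 fell too, with log2 fold changes of -0.83 and -0.71. Nppa, the atrial natriuretic peptide, did not pass (0.15). The median of the list was -0.63 and the mean -1.81, and camera did not call it (adjusted p = 0.13). Camera called it lower with Ensembl features alone (adjusted p = 0.00893) and after the length and GC correction (adjusted p = 0.00387), not so with an estimated correlation (adjusted p = 0.6 and 0.763).

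**Figure D3:**
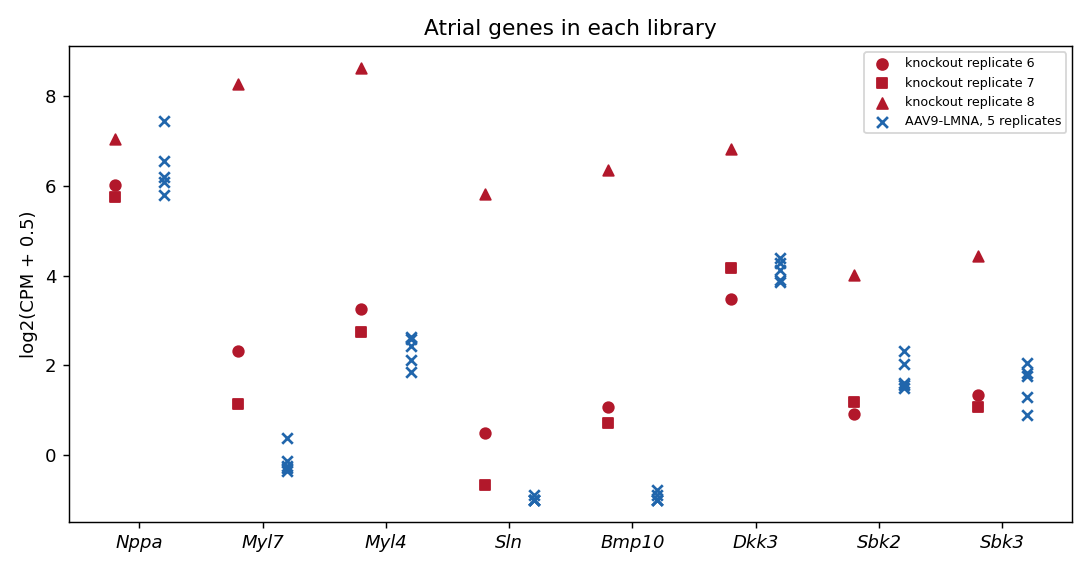
Atrial genes in each library as log2(CPM + 0.5). Red symbols are the 3 untreated libraries and blue crosses the 5 AAV9-LMNA libraries. Myl7, Myl4, Sln and Bmp10 in untreated replicate 8 (308, 399, 56.2 and 82.1 CPM) stand far above all other libraries.

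Genes of oxidative metabolism rose. Of 76 nuclear genes of oxidative phosphorylation, 59 rose, 0 fell and 17 were not called, with a median log2 fold change of 0.505 (61 rose adjusted over the list alone). Ndufa10 and Ndufb7, subunits of complex I, rose by 0.62 and 0.64, and Sdhb of complex II by 0.60. Camera called the list (adjusted p = 1.03e-20), and the call was lost with adjusted p = 0.0701 with an estimated correlation. With Ensembl features scaled alone 25 rose and the median was 0.30. After the correction for transcript length and GC content 2 rose and the median was 0.03, and camera no longer called the list (adjusted p = 0.139).

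That correction matters for short and long genes. Across 11600 coding genes with a log2 CPM above 1, the log2 fold change fell with transcript length (Spearman rho = -0.45 across genes, which are not independent replicates). The shortest of 5 length classes had a median log2 fold change of 0.41, with 849 called higher and 24 lower. The longest class had one of -0.05, with 122 higher and 433 lower. The slope of expression on the log2 length was positive in all 3 untreated libraries, 0.172 in replicate 6, 0.0754 in replicate 7 and 0.134 in replicate 8. It was negative in all 5 AAV9-LMNA libraries, from -0.1004 to -0.0613. After the correction 1256 genes were called, 340 higher and 916 lower.

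**Figure D4:**
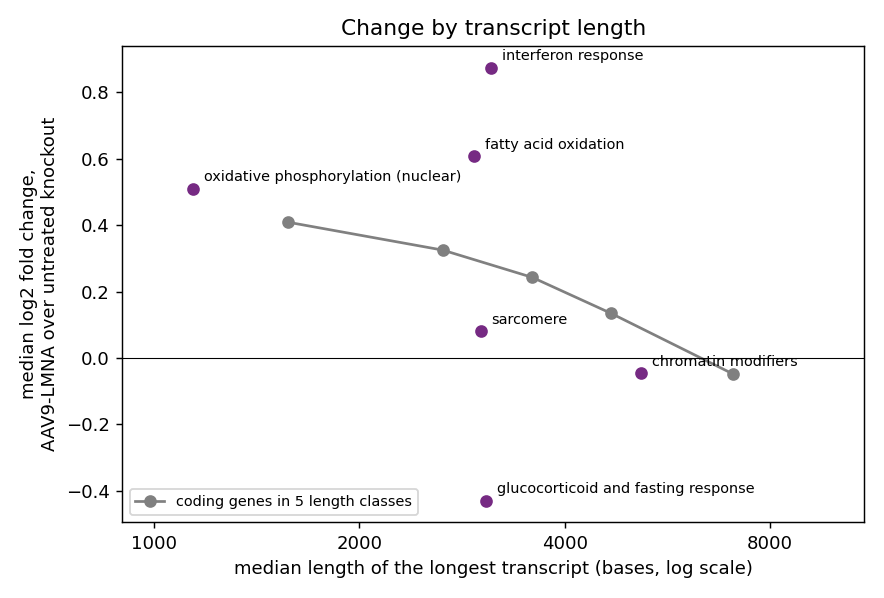
Median log2 fold change against the median length of the longest transcript (bases, log scale). Grey points are 5 equal classes of 11600 coding genes by length, from 0.41 in the shortest to -0.05 in the longest, and purple points are fixed lists, members with a log2 CPM above 1. Fatty acid oxidation (0.61) and interferon response (0.87) lie above genes of like length, and the glucocorticoid list (-0.43) lies below.

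Of 34 genes of fatty acid oxidation, the main fuel use of the heart after birth, 18 rose, 3 fell and 13 were not called (22 rose and 3 fell adjusted over the list alone), with a median of 0.61. Acadvl and Acadm, acyl-CoA dehydrogenases, rose by 0.70 and 0.57, and Hadhb of the mitochondrial trifunctional protein by 0.80. Fabp3, the heart fatty acid binding protein, had a log2 fold change of 1.34. Ppargc1a, a coactivator of mitochondrial genes (chromosome 5, 51454250 to 51567726), went the other way, from 260 ± 22.7 CPM (SD, n = 3) to 114 ± 29.2 (SD, n = 5), a log2 fold change of -1.20 with a standard error of 0.17 (edgeR adjusted p = 0.0025), and -1.22 after the length and GC correction. Camera called the list higher (adjusted p = 5.20e-07), not so with an estimated correlation (adjusted p = 0.564). With Ensembl features alone 12 rose, and 5 rose and 4 fell after the length and GC correction, where the median was 0.28.

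Of 23 glycolysis genes 9 rose, 1 fell and 13 were not called (10 and 2 adjusted over the list alone). Eno3 and Tpi1 rose by 0.55 and 0.52. The call of camera (adjusted p = 0.00779) was lost with an estimated correlation (adjusted p = 0.564), and with Ensembl features alone 1 gene rose and 1 fell. Of 13 mitochondrially encoded genes on the list only 6 passed the filter, of which 1 rose and 2 fell (2 and 2 adjusted over the list alone). mt-Nd4 and mt-Nd2, subunits of complex I, fell with log2 fold changes of -1.21 and -0.70, and mt-Co1 of complex IV rose by 0.35, which was -0.03 and not called after the length and GC correction. mt-Nd4 overlaps mt-Nd4l, and mt-Nd2 and mt-Co1 overlap other annotated genes too, so their counts are uncertain. The median was 0.10 and the mean -0.04, and camera did not call the list (adjusted p = 0.568). After the correction the median was -0.30, 3 fell, and camera called it lower (adjusted p = 0.0112), not so with an estimated correlation (adjusted p = 0.662).

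Chromatin modifier genes were called both ways. Of 66 chromatin modifier genes 12 fell, 10 rose and 44 were not called (13 and 13 adjusted over the list alone). Kmt2d (chromosome 15, 98831669 to 98871204), a histone H3 lysine 4 methyltransferase, went from 356 ± 40.3 CPM (SD, n = 3) to 113 ± 9.66 (SD, n = 5), a log2 fold change of -1.65 with a standard error of 0.10 (edgeR adjusted p = 4.3e-05). Kdm6b, a histone H3 lysine 27 demethylase (chromosome 11, 69398508 to 69413675), fell by 1.71, and the acetyltransferase gene Ep300 (chromosome 15, 81585351 to 81652077) had a log2 fold change of -1.0. Its relative Crebbp had a log2 fold change of -1.01, Kmt2a of -1.03 and Kmt2c of -0.82. Ep300 and Kdm6b overlap annotated noncoding genes. The 10 that rose had log2 fold changes of 0.27 to 1.46, among them the histone deacetylase genes Hdac2 (0.41), Hdac3 (0.40), Hdac10 (0.48) and Hdac11 (0.65), named after their values were seen.

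Both other fits use Ensembl features alone and move the median feature by -0.19 and -0.24, which favours falls over rises. With Ensembl features alone 16 fell, among them all 12, and 0 rose. After the length and GC correction 11 fell and 1 rose, and 9 of the 12 stayed called, with Kmt2d at -1.16, Kdm6b at -1.62 and Ep300 at -0.83. Camera did not call the list in the main test (adjusted p = 0.332), and called it lower with Ensembl features alone (adjusted p = 9.28e-07), a call lost with an estimated correlation (adjusted p = 0.728). Fry did not call it (adjusted p = 0.0565). Of 33 nuclear envelope genes 4 rose and 2 fell (3 and 1 adjusted over the list alone). Icmt, a carboxyl methyltransferase that acts on prelamin A, and the inner membrane protein genes Lemd2 and Plpp7 rose by 0.34, 0.31 and 0.47, and Tor1aip1 fell by 0.60. Camera did not call this list (adjusted p = 0.105) and fry called it higher (adjusted p = 0.0204), 0 rose with Ensembl features alone, and the median of 0.10 was -0.09 there.

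Interferon-induced genes were higher in AAV9-LMNA hearts. Of 49 genes 16 rose, 0 fell and 33 were not called (21 rose adjusted over the list alone), with a median of 0.91. The guanylate-binding protein gene Gbp4 rose by 1.03, the immunoproteasome gene Psmb8 by 1.30 and Ifit2 by 0.96. Gbp4 overlaps Gbp8 and Gbp9. Camera called the list (adjusted p = 6.06e-12), not so with an estimated correlation (adjusted p = 0.564). The untreated libraries differed among themselves: without replicate 7, 45 of the genes rose and the median was 1.58, without replicate 6, 5 rose and the median was 0.60, without replicate 8, 6 rose, and without replicates 6 and 8, 1 rose and the median was 0.20. Without AAV9-LMNA replicate 2, 3 or 4, 4, 7 and 6 rose. With Ensembl features alone 4 rose (median 0.75). Beside this list, markers of macrophages (median 0.73, 0 of 19 called) and lymphocytes (median 1.17, 4 of 13 called) had medians above 0. Neither marker list was called by camera with an estimated correlation (adjusted p = 0.661 each). The macrophage list turned lower without untreated replicates 6 and 8. Whether immune cells or the AAV9 vector itself underlie the interferon rise was not tested.

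The count of cell cycle genes called higher depended on single libraries of both groups. Of 50 genes 6 rose, 0 fell and 44 were not called (0 adjusted over the list alone), with a median of 0.64. The replication licensing gene Mcm6 rose by 1.62, the spindle checkpoint gene Bub1b by 1.59 and the mitotic kinase gene Cdk1 by 1.51. Camera called the list (adjusted p = 3.99e-06), not so with an estimated correlation (adjusted p = 0.694). Without untreated replicate 7, 28 rose, without replicate 6, 2, and without replicate 8, 0. Without AAV9-LMNA replicate 1, 10 rose, without replicate 2, 3 or 4, 1 each, and without replicate 5, 2. With Ensembl features alone 1 rose. Of 35 genes of inflammatory cytokines and chemokines 0 rose and 1 fell, Nfkbia, an inhibitor of NF-kappa-B, at -0.49 (also adjusted over the list alone). Camera did not call that list (adjusted p = 0.128).

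Markers of immune and endothelial cells were higher as lists. All 4 camera calls among 14 cell type lists were higher: endothelial (adjusted p = 0.00476), macrophage and monocyte (0.00238), lymphocyte and thymus (0.00158) and adipocyte (0.0114). With an estimated correlation 0 of the 14 lists were called, each of the 4 at adjusted p = 0.661, and 0 with fry (at an unadjusted p under 0.05, 0 and 3). Of 19 endothelial markers 6 rose and 2 fell (7 and 2 adjusted over the list alone), with Cldn5, a tight junction gene, at 1.2 and the receptor gene Tie1 at 0.67. Of 19 macrophage markers 0 were called by edgeR, over all features or adjusted over the list alone, and the median was 0.73. At an unadjusted p under 0.05 edgeR gave 2, and DESeq2 called 2 and limma-voom 6 at an adjusted p under 0.05. Ccr2 (1.56) and Cd68 (0.94) had the smallest p. Of 13 lymphocyte and thymus markers 4 rose (6 adjusted over the list alone), among them Ighm, the heavy chain of immunoglobulin M, at 1.59. It held 3.66 ± 2.21 CPM (SD, n = 3) in untreated and 10.97 ± 1.04 (SD, n = 5) in AAV9-LMNA libraries. Of 6 adipocyte markers 3 rose (3 adjusted over the list alone): Cidea (0.76), Lipe (0.54) and Fabp4 (0.65), which also stands on the endothelial list. With Ensembl features alone the endothelial and adipocyte lists were not called (camera adjusted p = 0.247 and 0.0754). There 1 endothelial marker rose and 2 fell, and 1 lymphocyte and 1 adipocyte marker rose. After the length and GC correction 1 endothelial marker rose and 1 fell, 1 lymphocyte marker rose and 0 adipocyte markers did.

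The other cell type lists were not called by camera. Of 17 fibroblast markers 0 were called by edgeR (0 at an unadjusted p under 0.05, 0 called by DESeq2 and 1 by limma-voom; median 0.17), with Dcn at 0.21, and of 14 epicardial markers 0 (0 at an unadjusted p under 0.05 and 0 by both other tools; median -0.47), with Wt1 at 0.42. Of 16 smooth muscle and pericyte markers 2 rose, Des (0.33) and Ndufa4l2 (0.53), and 0 did adjusted over the list alone. Of 7 lymphatic markers 2 fell, Reln (-0.66) and Prox1 (-0.68), as they did adjusted over the list alone. Of 10 neutrophil and mast cell markers 2 rose, the mast cell protease genes Cpa3 and Mcpt4, both under 1 CPM in each group mean (also 2 adjusted over the list alone). In 4 lists 1 gene was called, over all features and adjusted over the list alone, among them Ckm of 9 skeletal muscle markers (0.61) and Ahsg, a liver gene, of 4 lung and liver markers (-1.73). The camera adjusted p of these 9 lists ran from 0.117 to 0.686.

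Several targets of glucocorticoids were lower. Of 19 genes on the glucocorticoid and fasting list 6 fell, 2 rose and 11 were not called (7 and 2 adjusted over the list alone), with a median of -0.51. Cdkn1a, a cell cycle inhibitor that p53 also induces (chromosome 17, 29090976 to 29100727), went from 61.9 ± 21.02 CPM (SD, n = 3) to 23.4 ± 1.75 (SD, n = 5), a log2 fold change of -1.40 with a standard error of 0.19 (edgeR adjusted p = 0.00205). Zbtb16 and Per1 had log2 fold changes of -1.06 and -0.94, and Fkbp5, which binds the receptor complex, one of -1.75. The risers were Angptl4 (2.17) and Dusp1 (1.01). Camera missed the threshold (adjusted p = 0.105, and 0.694 with an estimated correlation). It called the list lower with Ensembl features alone (adjusted p = 0.00149) and after the length and GC correction (adjusted p = 0.00021), where 7 fell, and both calls were lost with an estimated correlation (adjusted p = 0.728 and 0.662).

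Of 29 p53 targets 0 rose and 2 fell, Cdkn1a and Zmat3 (-1.13), as they did adjusted over the list alone, while the list median was 0.29 and camera did not call it (adjusted p = 0.239). Of 27 FOXO targets 4 rose and 3 fell (4 and 3 adjusted over the list alone), with Sod2 (0.45) and Gadd45a (0.76) higher and the insulin receptor gene Insr (-0.96) and Ddit4 (-0.63) lower (camera adjusted p = 0.49). With Ensembl features alone 1 of them rose and 4 fell. After the length and GC correction 0 rose and 2 fell, and the calls of Sod2, Gadd45a and Insr were lost. Of 30 integrated stress response genes 5 rose and 0 fell (5 adjusted over the list alone), among them the mitochondrial protease gene Lonp1 (0.68) and the tRNA synthetase genes Sars (0.44) and Gars (0.44). Camera called this list (adjusted p = 0.00416), not so with an estimated correlation (adjusted p = 0.564). Of 36 autophagy and lysosome genes 13 rose and 3 fell (14 and 3 adjusted over the list alone), with Gabarap (0.56) and Becn1 (0.54) higher and Atg13 (-0.78) and the cholesterol transporter gene Npc1 (-0.52) lower. Camera called it (adjusted p = 0.0036, and 0.418 with an estimated correlation). With Ensembl features alone neither list was called, and 1 and 4 genes rose.

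Sarcomere and ion channel genes went both ways in the main test. Of 27 sarcomere genes 5 rose and 5 fell (6 and 5 adjusted over the list alone). Myoz2, a Z-disc protein gene, rose by 0.65, and Synpo2l and Actn2 fell with log2 fold changes of -0.91 and -0.43. Ttn, the longest gene of the list, fell by 0.77 and was at 0.20 and not called after the length and GC correction. Camera did not call the list (adjusted p = 0.49), and its median of 0.08 was -0.13 with Ensembl features alone, where 0 rose and 5 fell. After the length and GC correction 0 rose and 3 fell, and Myoz2 was at 0.345 and not called (edgeR adjusted p = 0.178). Both fits shift the scale towards falls. Of 36 ion channel and calcium handling genes 6 rose and 1 fell (5 and 1 adjusted over the list alone), with the pacemaker channel gene Hcn2 at 0.62, the calcium pump gene Atp2a2 at 0.39, Casq2 at 0.39 and the L-type calcium channel gene Cacna1c at -0.64. Camera did not call it (adjusted p = 0.275), and the median of 0.06 was -0.14 with Ensembl features alone, where 1 rose and 3 fell. After the length and GC correction 1 rose, Hcn2 (0.42), and 0 fell. Atp2a2 (0.34), Casq2 (0.07) and Cacna1c (-0.36) were not called there.

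Of 22 cardiac stress and fetal genes 0 rose and 4 fell (3 adjusted over the list alone): Myl7 and Myl4, which also stand on the atrial list, Xirp1 (-0.63) and Ccn2 (-0.71). The natriuretic peptide gene Nppb held 91.2 to 380 CPM in untreated and 121 to 200 CPM in AAV9-LMNA libraries. Camera did not call the list (adjusted p = 0.872). Of 41 extracellular matrix genes 0 rose and 2 fell, Lox (-0.79) and Timp3 (-0.74), 0 adjusted over the list alone (camera adjusted p = 0.146). Of 26 TGF-beta targets 1 rose and 2 fell, Id1 (0.45), Ccn2 and Ltbp3 (-0.49), 0 adjusted over the list alone (camera adjusted p = 0.239).

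**Figure D5:**
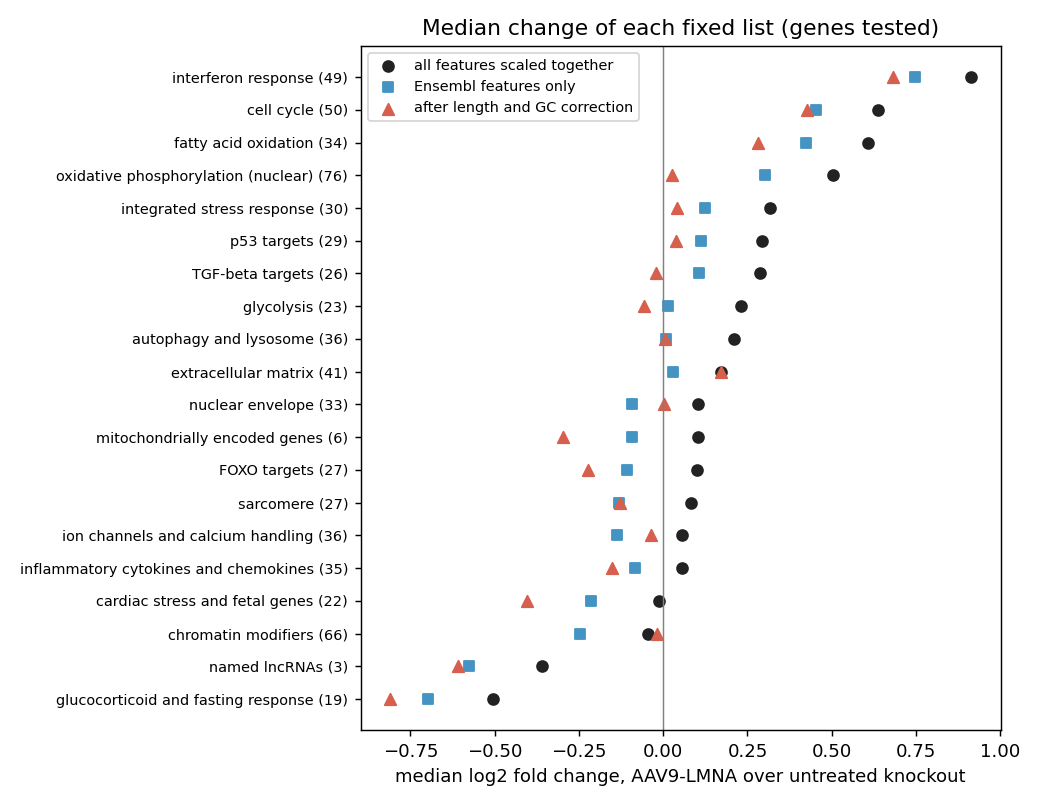
Median log2 fold change of each pathway list (number of genes tested in brackets) with all features scaled together (black), Ensembl features alone (blue squares) and after the length and GC correction (red triangles). Oxidative phosphorylation moves from 0.505 to 0.03, and interferon response stays between 0.68 and 0.91.

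NONCODE long noncoding features fell as a class. Of 11461 tested 3231 changed, 95.4% of them lower, with a median log2 fold change of -0.61 (edgeR quasi-likelihood, adjusted over all 26717 features). The class moved with the share of reads outside features, which was 1.60 times as high in untreated libraries. Relative to other NONCODE features, in the fit of these features alone, 902 were higher and 883 lower of 11104 tested. Untreated replicate 6 carried much of the count: without it 1489 were called, 1385 of them lower. Without AAV9-LMNA replicate 2 or 3, 2046 and 2108 were called.

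The feature NONMMUG035083.2 fell from 83.7 ± 6.27 CPM (SD, n = 3) to 33.5 ± 4.19 (SD, n = 5), a log2 fold change of -1.32 with a standard error of 0.11 (edgeR adjusted p = 0.00014). NONMMUG001406.2 and NONMMUG038281.2 fell too, with log2 fold changes of -1.80 and -2.51. Rises were found in NONMMUG020347.3, from 7.57 ± 0.762 to 15.3 ± 1.06 CPM, at 1.02, and in NONMMUG032832.3 (1.33) and NONMMUG086053.1 (0.81). All 6 were called in the fit of NONCODE features alone. Ensembl long noncoding genes could hardly be tested: 8786 of 9257 (94.9%) had a count of 0 in all 8 libraries, against 17.5% of coding genes. A read that overlaps an Ensembl and a NONCODE gene is dropped as ambiguous, so a count of 0 does not show that an RNA is absent. How far such dropped reads account for these counts was not tested. Of 47 named long noncoding RNAs counted, 42 were at 0 throughout, among them Xist, Malat1, Neat1, Meg3 and H19. The 3 that passed the filter were not called by edgeR over all features or adjusted over the list alone (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), with Dleu2 at -0.66 and Hand2os1 at -0.36 (camera adjusted p = 0.568).

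Over all 20 pathway lists, camera called 7 with its preset correlation, all higher: oxidative phosphorylation, fatty acid oxidation, glycolysis, cell cycle, integrated stress response, interferon response, and autophagy and lysosome. With an estimated correlation 0 were called (1 at an unadjusted p under 0.05), and with fry 5, of them 4 of the 7 and nuclear envelope. After the length and GC correction camera called 6: fatty acid oxidation, cell cycle and interferon response higher, and mitochondrially encoded genes, the glucocorticoid list and chromatin modifiers (adjusted p = 0.0497) lower. With an estimated correlation 0 were called in that fit (adjusted p of at least 0.662). Without untreated replicates 6 and 8, where the single remaining untreated library is assumed to vary like the others, 11 pathway lists were called, 4 of the 7 among them.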

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

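Within the 5 AAV9-LMNA libraries, 124 values (genes named by the fixed rule, 8 further genes and 3 library measures) were tested for a library far from the other 4, as the gap to its nearest neighbour over the whole range (Dixon's ratio, 95% critical value 0.71). Chance passes about 1 in 20, the values are not independent, and 19 passed. The further genes were chosen after the data were seen. Groups of 3 libraries were not tested.

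AAV9-LMNA replicate 1 was the outlying library for 12 of the 19. It held almost no transcripts of the Y chromosome genes Ddx3y (ratio 0.923; 0.187 CPM against 141 to 153 in the other 4 and 112 to 137 in untreated libraries), Eif2s3y (0.828; 0.0467 against 42.6 to 51.5 CPM) and Uty (0.844; 0.0467 against 49.5 to 58.6 CPM). Xist was at 0 in every library, as were most Ensembl long noncoding genes, and could not be set beside them. By its Y chromosome genes replicate 1 was the only library that reads as female, and whether sex underlies its other outlying values was not tested. It lay nearer to the untreated libraries than the other 4 did for Hif3a (0.755; 5.98 CPM against 1.66 to 2.72, untreated 6.57 to 25.4), Ccn2 (0.8; 152 against 89.4 to 102, untreated 138 to 202), Synpo2l (0.812; 187 against 116 to 130, untreated 210 to 294), Ppargc1a (0.789; 165 against 92.9 to 108, untreated 237 to 282) and Pgk1 (0.784; 15.9 against 20.7 to 22.1, untreated 10.5 to 15.05). The same held for Ep300 (0.747; 61.3 against 54.6 to 56.3, untreated 99.8 to 125) and Prox1 (0.726; 64.4 against 36.2 to 43.9, untreated 49.8 to 92.9). It lay farther from them for Myoz2 (0.767; 2740 CPM against 1832 to 2044, untreated 1230 to 1430) and Cdkn1a (0.831; 20.3 against 23.9 to 24.7, untreated 38.3 to 78.7).

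AAV9-LMNA replicate 5, which had the most Lmna, was the outlying library for 3. It was lowest for H2-T23 (0.712; 3.62 CPM against 10.1 to 12.7) and Ifit2 (0.729; 16.7 against 28.5 to 32.9), and highest for the T cell kinase gene Lck (0.865; 2.22 against 0.530 to 0.759). Its values of H2-T23 and Ifit2 lay just above the highest untreated libraries (2.77 and 16.1 CPM). AAV9-LMNA replicate 3 was highest for Lonp1 (0.734; 283 CPM against 245 to 255) and Dleu2 (0.945; 0.806 against 0.408 to 0.429). AAV9-LMNA replicate 2 was highest for Myl7 (0.734; 0.796 CPM against 0.285 to 0.421), and replicate 4 for NONMMUG035083.2 (0.776; 40.8 against 30.7 to 32.9).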

How the results depend on the processing

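The correction for length and GC content, the fit without untreated replicates 6 and 8 and the estimated correlation with Ensembl features alone were chosen after the data were seen; the rest were set beforehand. No paired analysis was possible because the groups share no replicate number. The Xist covariate was not run because Xist was at 0 in every library. The cause of the changes below was not tested unless stated.

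Counts of changed features were 6994 with RLE factors, 7927 with DESeq2, 6923 with limma-voom, 8283 with no filter and 5737 at 1 CPM, within 1.5 times the 6858. They were 4330 with 1 surrogate variable, and 2143 without replicates 6 and 8, where fewer libraries enter. Ensembl features made up 3627 of the 6858. Without NONCODE features, 1967 were called with Ensembl features alone and 1256 after the length and GC correction. Leaving out each library in turn gave 4216 to 10033, lowest without AAV9-LMNA replicate 2 and highest without untreated replicate 7. NONCODE calls were 3231 in the main test, 1785 with NONCODE features alone, 1493 with 1 surrogate variable and 475 without replicates 6 and 8. They ran from 1489 (without untreated replicate 6) to 4343 (without untreated replicate 7) with each library left out. Lmna had a log2 fold change of 2.67 to 3.36 with each library left out, called each time. Without replicates 6 and 8, with the single untreated library assumed to vary like the others, it was 2.56 and not called (edgeR adjusted p = 0.191).

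Pathway lists called were 7 in the main test, 14 with no filter, 0 with an estimated correlation (also 0 with Ensembl features alone), 5 with fry (4 of the 7), 6 after the length and GC correction (3 of the 7, and 3 others lower) and 11 without replicates 6 and 8 (4 of the 7, 2 others higher and 5 lower), and 7 to 12 with each library left out (12 without untreated replicate 7). Cell type lists called were 4 in the main test, 8 with no filter, 1 at 1 CPM, 2 with 1 surrogate variable, 0 with an estimated correlation (also 0 with Ensembl features alone), 0 with fry, 4 after the length and GC correction (macrophage and lymphocyte higher, and atrial and lung and liver lower, adjusted p = 0.00387 and 0.0293; all 4 lost with an estimated correlation, adjusted p = 0.763) and 1 without replicates 6 and 8, and 4 to 6 with each library left out. The extracellular matrix list turned lower with 1 surrogate variable (camera adjusted p = 0.0304). Without replicates 6 and 8, the inflammatory (camera adjusted p = 1.57e-08), p53 (0.0085), TGF-beta (0.0304) and macrophage (0.325) lists turned lower. After the length and GC correction Ttn (0.20), mt-Co1 (-0.0293), Id1 (-0.0138) and Shmt2 (-0.0242) changed sign and were not called (edgeR adjusted p = 0.324 to 0.959); that fit moves the median feature by -0.24, and with the shift taken off the last 3 stay above 0 (0.22 to 0.23). Of 112 named genes, 110 kept direction and side of the threshold with RLE factors, and calls lost in the same direction were 51 without replicates 6 and 8, 40 after the length and GC correction, 29 with Ensembl features alone, which that correction also uses, 27 with 1 surrogate variable, and 4 to 22 with each library left out. In the simulation, with 112 calls in all, changes of 1.5-fold were recovered in 4.48% of 67 genes. The main test made 6858 calls, so its cut on p was less strict and that share does not carry over to it. An uncalled gene may still have changed.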

Other observations

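The gene families below, the tests of atrial and stress genes in untreated replicate 8, the comparison of oxidative phosphorylation with all coding genes, the count of chromatin modifier genes and the oxidative phosphorylation median with the shift of scale taken off, and the comparisons of sarcomere genes before the correction were chosen only after the result was seen; the other tests were set before it.

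Of 7 gene families counted outside the fixed lists, the 5 below had nearly all calls higher, and zinc finger and splicing factor genes had calls both ways. No list test was run on them, and the fits with Ensembl features alone and with the length and GC correction move the median feature by -0.19 and -0.24, which by itself lowers the number of rises. Of 74 genes of mitochondrial ribosomal proteins 57 rose and 0 fell (edgeR quasi-likelihood, adjusted p under 0.05; median 0.50), which became 22 with Ensembl features alone (median 0.31) and 3 after the length and GC correction (median 0.18). Of 48 proteasome subunit genes 25 rose and 1 fell (median 0.37), then 8 and 1 (0.18), then 2 and 1 (0.01). Of 92 cytosolic ribosomal protein genes 16 rose and 1 fell (median 0.37), then 4 and 1, then 0 and 2. Of 42 mitochondrial carrier genes (Slc25a) 11 rose and 0 fell, then 3 rose and 3 fell in both other fits.

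Of 14 H2 genes of the major histocompatibility complex 4 rose and 0 fell (median 1.24), with 3 called at medians of 1.08 and 0.90 in the other fits.

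NONCODE features were lower with AAV9-LMNA as a class, together with reads outside features. Genomic DNA in the untreated libraries would raise reads on 1447 autosomal olfactory and vomeronasal receptor genes by at least the factor seen outside features, 1.60. Their summed CPM was 38.2 ± 8.14 (SD, n = 3) in untreated and 36.4 ± 3.6 (SD, n = 5) in AAV9-LMNA libraries, a ratio of 1.047 ± 0.137 (standard error), which argues against it. Unspliced precursor RNA may account for part of the pattern. Ensembl features not annotated as protein coding had a median log2 fold change of -0.26 inside coding genes but off their exons (589). Outside coding genes (787) it was 0.30. The difference was -0.56 ± 0.04 (standard error over features, not libraries) and -0.61 after the length and GC correction. Permutation of features gave p = 1e-04, the smallest 10000 permutations give. Only 91 Ensembl long noncoding genes passed the filter, so most of these features are of other classes. The sets were not matched on class, so precursor RNA and a difference between classes cannot be told apart. NONCODE features themselves could not be placed in the genome here, and a change in nuclear RNA that follows from the LMNA vector, or a difference in RNA handling between the groups, was not tested.

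The trend with transcript length bears on oxidative phosphorylation and on chromatin modifiers in different ways. The oxidative phosphorylation median was 0.505 with all features scaled together and 0.30 with Ensembl features alone, beside 0.22 and 0.03 for all coding genes. After each library was also corrected for length and GC content it was 0.026 ± 0.028 (standard error), 0.012 above that of all coding genes, and 0.27 with the shift of the median feature (-0.24) taken off, where under 0.1 was set beforehand for the trend as cause and over 0.25 against it. The trend could thus account for the rise of this list above other coding genes, while the part shared with all coding genes depends on the scale and stays open. Against 10000 lists matched only on classes of length and level its median lay above all of them (0.51 against 0.37), which leaves a part open. A larger share of cardiomyocytes should move sarcomere genes alike. The difference of medians (sarcomere minus oxidative phosphorylation) was -0.42 ± 0.12 (standard error) in the fit that shows the rise, with 5 of 27 sarcomere genes higher and 5 lower. It was -0.28 when each list is set against lists matched on length and level, and -0.155 ± 0.059 after the correction, just past the 0.15 set beforehand. These errors, like that of the oxidative phosphorylation median, resample genes, which are not independent replicates, and leave out the spread between libraries. The values thus lean against a larger share of cardiomyocytes as the cause but do not settle it. Of the 12 chromatin modifier genes called lower, 9 stayed so after the correction, just the 3 in 4 set beforehand, in a fit that also moves the median feature down by 0.24. With that shift taken off, 8 of the 12 still lay below 0 by 2 standard errors. Among them were Kmt2d at -0.92, Kdm6b at -1.38 and Ep300 at -0.59. The 12 were picked for their falls in these same libraries, which favours that count. It thus leans against the length trend as the whole cause for these 8 but does not settle it, and leaves it open for the other 4. The full list, not picked by its values, had a median of -0.05 in the main test (members with a log2 CPM above 1). Of 10000 lists matched on length and level, with a median of 0.07, 0.71% lay lower, a comparison with no bound set beforehand. An effect of LMNA or of the vector, and a library batch that follows the groups, stay open and untested.

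Atrial genes were high in untreated replicate 8. The median over 17 genes of the atrial list, as log2(CPM + 0.5) in replicate 8 minus the mean of replicates 6 and 7, was 1.34 ± 0.88 (standard error over genes, here and below), with 10 genes over 1 and a percentile of 100 among 10000 lists matched on expression. Myl7, Myl4, Sln and Bmp10 prompted this test, and without them the median over 13 genes was 0.87 ± 0.42, under the 1 asked for. Atrial tissue in that library thus stays open. The full list passed the 1 asked for, and without the genes that prompted the test it did not. Of these 13, 6 were over 1, among them Sbk3 (3.23), Dkk3 (3.00), Sbk2 (2.95) and Stard10 (2.15), and Clu (-0.75) and Kcnk3 (-0.41), list members with high counts in every library, were not raised there. A stress response of ventricular myocytes would raise the stress list without the atrial genes, and its median over 19 genes was -0.41 ± 0.29, which argues against it. Sln, at 56.2 CPM there, 0.902 and 0.128 in the other untreated libraries and 1 count over all AAV9-LMNA libraries, was named after its values were seen. Whether the atria were dissected alike is not given in the sources used here.

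All 56 splits of the 8 libraries into 3 and 5 were refitted. For the 6858 changed features, 1 split of the 56, the real one, gave as many, and the highest other split gave 89. That is the smallest share 56 splits can give, so a chance split is unlikely as the origin of that count but not excluded. The other splits hold the group difference within their groups, which adds to their spread, so the gap to 89 adds no evidence. A batch that follows the groups would pass the same test. For the 3231 NONCODE calls it was again 1, with 11 the highest other. For the 7 pathway lists called by camera at its preset correlation, 40 splits gave as many (highest other 12), and for the 4 cell type lists 51 did (highest other 12), so for both counts of lists chance cannot be excluded.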
